A study of Homo sapiens with 30 samples.

How the data were processed

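The series holds 15 human samples measured on A and B arrays of an Affymetrix pair, 30 arrays in all: 3 ITTP, 2 DP, 3 SP4, 2 CB4, 3 AB4 and 2 TSC samples on each array type. Per the labels, the T lineage cells were obtained by fluorescence-activated sorting and total RNA was used. The deposited values are log2 intensities, 1 per probe set and array. They run from 3.36 to 13.97 on A arrays and from 3.01 to 13.78 on B arrays. The software that made them, and its settings, are not given in the sources used here.

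Array A and array B of the same title number were taken as 1 sample. This was checked on 100 probe sets present on both types: for each of the 15 samples, the best match of its A array was its own B array. The labels do not say whether replicates came from separate donors, so the p-values measure only the spread between these samples. The number of arrays limits the precision of each value.

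Arrays of a type were to be left as they were where the 2% trimmed means of their linear values lay within 10% of each other, and otherwise quantile normalized. The trimmed means differed by up to 16.0% on A arrays and 12.0% on B arrays, so both types were quantile normalized, which moved values by at most 0.25 and 0.37 on the log2 scale. Values as deposited were used as an alternative, chosen after the arrays' scale was seen.

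Probe sets were named from the array annotation, with current symbols taken from the RefSeq gene table of the human assembly, used for names alone. Of 22283 probe sets on the A array 19071 named exactly 1 gene, 1043 several and 2169 none, and of 22645 on the B array the numbers were 15432, 554 and 6659. A gene was represented by the brightest of its probe sets that name it alone, from the A array where it was present there, which gave 17486 genes (11939 from A and 5547 from B). A gene was tested where at least 2 arrays lay at or above the 40th percentile of all values of their type. Control probe sets and 52 sex-linked probe sets were left out. The filter level was 5.83 on A and 5.25 on B arrays. No detection calls were used, so a group mean below that level is not shown to be above background. Background, where it remains in a dim value, makes a change against such a mean look smaller. The words at least and lower bound refer to this alone. They do not take in the spread between samples. This left 13282 genes for the T lineage comparisons (9028 from A and 4254 from B).

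Differences were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per group and moderated variances, on A and B arrays separately. The 13 T lineage samples shared a fit for the comparisons of DP with ITTP, SP4 with DP, CB4 with SP4 and AB4 with CB4 and for the F-test across the 5 groups. The comparison of TSC with the mean of the ITTP, DP and SP4 group means used all 15 samples. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of both types together, with a threshold of 0.05. Because every consecutive comparison shares a group with the next, a group whose samples run high or low moves neighbouring comparisons in opposite directions.

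Gene lists, 30 in number, cover T cell development, signalling, metabolism and markers of other cell types that a gate or tissue could hold. Each list with at least 4 tested genes was tested with cameraPR of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry, both of limma, were run beside it. Named genes were, for each comparison, the 8 with the largest rise and the 8 with the largest fall among genes that passed and whose groups' arrays did not overlap, up to 5 genes of each list with the smallest p-values, and the sort markers. The groups, comparisons, lists, this rule and the alternatives, apart from those named as later choices, were fixed before the data were examined. RAG1, outside the rule where DP is compared with ITTP, is given there as a level.

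The alternatives covered array scale (a shift to a common 75th percentile, values as deposited), the filter on dim genes (none, or the 60th percentile), the arrays in the fit, the title number as a fixed factor, each probe set as its own feature, the median of a gene's probe sets, a mean-variance trend with robust moderation, array quality weights, adjustment within array type, a test against a fold change of 1.2 and leaving out each sample in turn. The pipeline was tested on simulated data with 200 changed genes in place of the real differences. It recovered from 64.2% to 79.1% of genes changed 2-fold and from 97.0% to 100% of those changed 4-fold over the 5 comparisons. The share of false calls ran from 2.99% to 7.59%, and was 6.90%, 7.59% and 6.75% for SP4 with DP, AB4 with CB4 and TSC with thymocytes, above the nominal 5%. Each share comes from a single run, so it cannot show whether the procedure exceeds 5% in general. The simulated noise was independent between genes, and fewer genes were changed than were called in the real comparisons. The recovered and false shares therefore need not hold for the real data.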

Results

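Gene expression was measured in total RNA from 15 human samples of 6 cell groups, each hybridized to an A and a B array of a pair, 30 arrays in all. The T lineage groups follow CD4+ T cell differentiation. Intrathymic T progenitors (ITTP, 3 samples) were sorted from fetal thymus as CD34low cells with CD4 but neither CD3 nor CD8 at the surface. Double-positive thymocytes (DP, 2 samples) carried CD4, CD8 and intermediate CD3, and single-positive thymocytes (SP4, 3 samples) carried CD4 and high CD3 without CD8. Naive CD4+ T cells, sorted by surface markers that include CD45RA, came from cord blood (CB4, 2 samples) and from adult blood (AB4, 3 samples). Thymic stromal cells (TSC, 2 samples) were the remaining group. Expression is given as log2 intensity with the SD between samples, and changes as log2 fold change with the SE from limma. The small number of arrays limits precision: the median SE of a change was 0.17 between T lineage groups and 0.15 between stromal cells and thymocytes. A group mean below the filter level, 5.83 on A and 5.25 on B arrays, is not shown to be above background. The words at least and lower bound mark a change against such a mean, and the genes concerned are named with each comparison. They do not take in the spread between samples, so such a change can also be smaller.

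Samples of a group resembled each other more closely than samples of different compartments. Across probe sets, which are not independent replicates, the correlation between arrays of the same group ran from 0.961 to 0.990, and that between stromal and T lineage arrays from 0.796 to 0.868. Different T lineage groups overlapped the same-group range. On A arrays pairs reached 0.978 between ITTP and DP and 0.976 between CB4 and AB4. Among the T lineage samples, the leading principal component held 50.6% of the variance and ordered the groups along differentiation. ITTP samples scored from -46.6 to -44.0 on it, DP samples from -40.3 to -33.7, SP4 samples from -2.05 to 13.6, CB4 samples from 33.7 to 34.7 and AB4 samples from 38.1 to 39.9. Expression of 4408 of 13282 tested genes (33.2%) differed across the 5 T lineage groups at an adjusted p under 0.05 in limma's F-test.

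**Figure D1:**
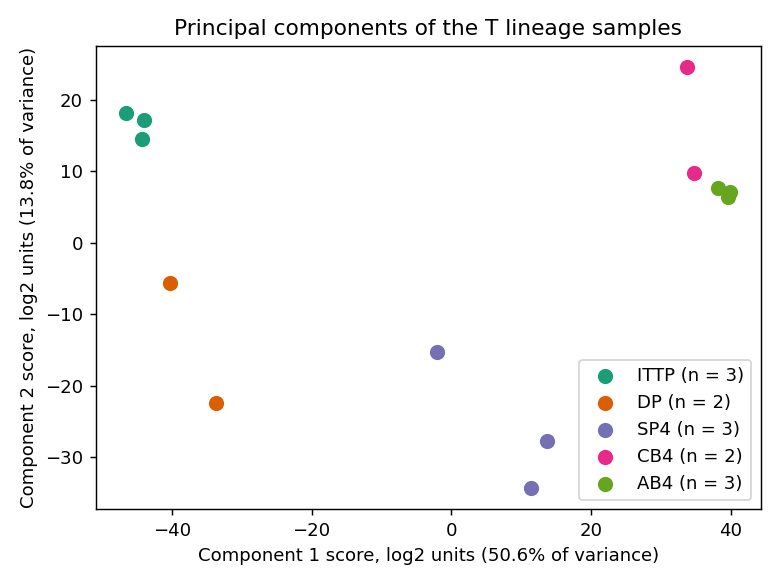
Each point is a T lineage sample, placed by its scores on component 1 (x axis, 50.6% of the variance) and component 2 (y axis, 13.8% of the variance), both in log2 units and colored by group. The ITTP samples lie between -46.6 and -44.0 on component 1 and the AB4 samples between 38.1 and 39.9.

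RNA of CD8A and CD8B was highest in the CD8+ DP gate. That of CD3D, CD3G and PTPRC separated T lineage from stromal cells. CD3D and CD3G RNA did not follow the surface CD3 of the thymocyte gates. CD8A, a chain of the CD8 coreceptor, averaged 12.27 ± 0.15 (SD, n = 2) in DP cells and lay between 6.23 and 8.03 in the other group means. CD8B averaged 13.21 ± 0.23 (SD, n = 2) in DP cells and 8.79 ± 0.81 (SD, n = 3) in ITTP. CD4 had group means from 6.67 in stromal cells to 7.77 in DP cells. CD3D, a chain of the T cell receptor complex, was already at 12.62 ± 0.29 (SD, n = 3) in ITTP cells, which lack surface CD3, against 13.11 ± 0.18 (SD, n = 2) in DP cells and 5.51 ± 0.06 (SD, n = 2) in stromal cells. CD3G averaged 10.92 in ITTP, 11.16 in DP and 10.77 in SP4 cells and 6.07 in stromal cells. The probe set used for CD3E varied little, from 7.19 in stromal cells to 7.69 in CB4 cells. Unlike those of CD3D and CD3G it hardly separated T lineage from stromal cells, so it is not shown to follow CD3E RNA. CD34, a progenitor antigen, averaged from 6.22 to 6.59 in all groups, ITTP included. Its probe set is likewise not shown to follow CD34 RNA. PTPRC, which encodes CD45, averaged from 9.85 to 11.40 in the T lineage groups and 5.17 in stromal cells.

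**Figure D2:**
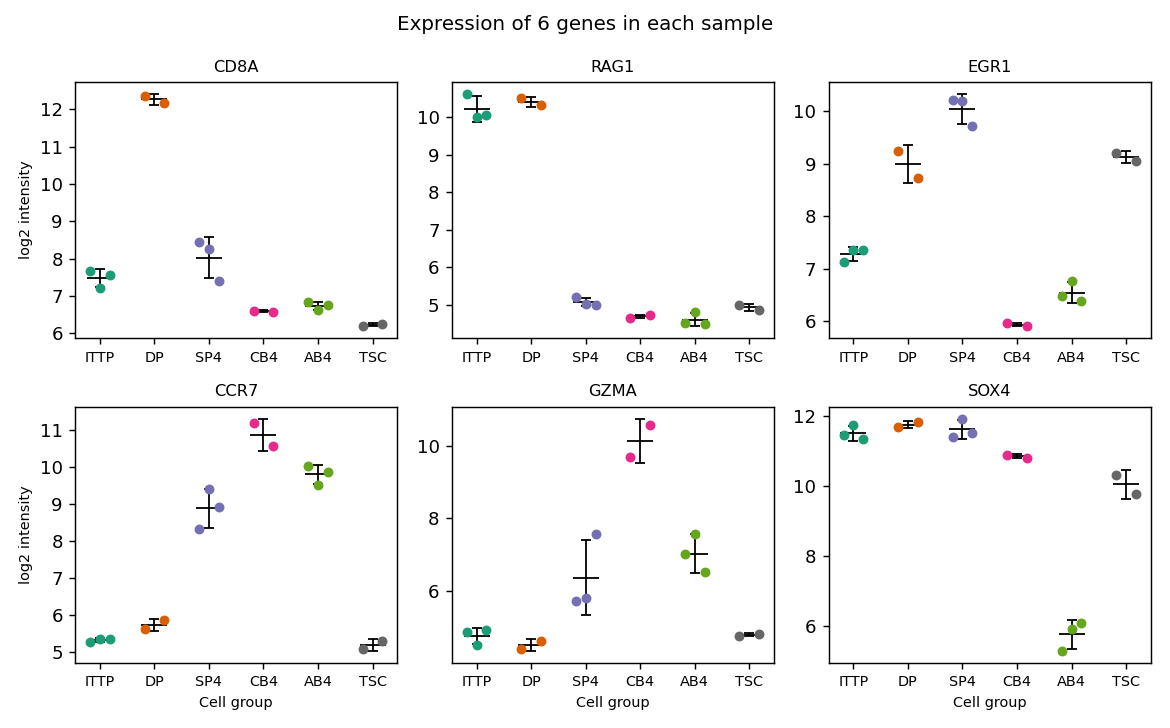
Points give the log2 intensity (y axis) of CD8A, RAG1, EGR1, CCR7, GZMA and SOX4 in each sample, grouped by cell type (x axis), and the bars show the group mean and SD. CD8A averages 12.27 in DP cells, CCR7 10.88 in CB4 cells, and SOX4 10.87 in CB4 against 5.76 in AB4 cells.

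The comparison of DP with ITTP cells asked what changes as CD4-bearing progenitors become double positive. Both CD8 genes rose, CD8A (probe set 205758_at) 27.6-fold and CD8B (207979_s_at) 21.3-fold, with log2 changes of 4.78 ± 0.25 (adjusted p = 2.03e-06) and 4.42 ± 0.39 (adjusted p = 8.97e-05). TOX2, a nuclear factor of the TOX family, rose at least 16.5-fold (228737_at), from 4.72 ± 0.16 (SD, n = 3) to 8.76 ± 0.23 (SD, n = 2). BCL6, a transcriptional repressor, rose 9.84-fold and SLAMF1, a surface receptor of lymphocytes, 11.4-fold. SOCS2, a suppressor of cytokine signalling, fell by 3.99 ± 0.32 on the log2 scale. PRKCA, a protein kinase C gene, fell by 2.79 ± 0.19, and JCHAIN, the joining chain of immunoglobulins, fell by 3.45 ± 0.17.

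Genes of the T cell receptor apparatus rose together in DP cells. Of 21 tested genes for the receptor complex and its proximal signalling, 8 rose and 13 did not pass (13 rose adjusted over the list alone), with a median log2 change of 0.76 (list adjusted p = 8.9e-15, and adjusted p = 0.0261 with an estimated correlation). CD28, the costimulatory receptor, rose by 2.20 ± 0.27, and TRBC1, a receptor beta chain gene, by 0.95 ± 0.11, while the adaptor LCP2 rose 2.83-fold. Genes of positive selection and receptor response also rose, 4 of 12 (9 rose and 1 fell adjusted over the list alone), among them EGR1, an immediate early transcription factor, by 1.71 ± 0.20 and ITM2A by 1.84 ± 0.30 (list adjusted p = 2.17e-07, and adjusted p = 0.0387 with an estimated correlation). Of 16 cortical thymocyte and V(D)J recombination genes, 7 rose (8 rose and 1 fell adjusted over the list alone), including CD1D, an antigen-presenting molecule, by 2.64 ± 0.27 and ARPP21 by 1.06 ± 0.12 (list adjusted p = 8.41e-15, and adjusted p = 0.0599 with an estimated correlation). RAG1, which cuts DNA in V(D)J recombination, averaged 10.22 in ITTP and 10.42 in DP cells. Of 14 immediate early and stress genes 3 rose, both over all genes and adjusted over the list alone (list adjusted p = 4.25e-05, and adjusted p = 0.0357 with an estimated correlation). On the NF-kB pathway list 2 of 11 rose, LTB, a lymphotoxin subunit, by 1.90 ± 0.16 and TNFAIP3, a feedback inhibitor, by 1.04 ± 0.13, and both also rose adjusted over the list alone (list adjusted p = 5.18e-04, and adjusted p = 0.0732 with an estimated correlation). On the recent thymic emigrant list, 2 of 8 rose, 3 adjusted over the list alone (list adjusted p = 0.0067, and adjusted p = 0.133 with an estimated correlation): CCR9, a chemokine receptor that thymocytes also carry, by 2.47 ± 0.34 and the ectoenzyme CD38 by 1.34 ± 0.17.

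Early progenitor and Notch genes were lower in DP than in ITTP cells. Of 13 tested, 4 fell (7 adjusted over the list alone), among them IGLL1, a surrogate light chain gene, at -1.37 ± 0.13 and NRARP, a Notch target, at -1.02 ± 0.14 (list adjusted p = 1.21e-08, and adjusted p = 0.0261 with an estimated correlation). Of 7 GIMAP genes, GTPases of lymphocytes, 2 fell (4 adjusted over the list alone), with a median of -0.68 (list adjusted p = 0.00137, and adjusted p = 0.13 with an estimated correlation). Of 27 interferon-stimulated genes 3 fell, 5 adjusted over the list alone (list adjusted p = 1.43e-04, and adjusted p = 0.13 with an estimated correlation). The MHC class II list passed as a whole (adjusted p = 3.05e-04, and adjusted p = 0.13 with an estimated correlation), although limma called 0 of its 10 genes over all genes tested. Adjusted over the list alone 6 of them fell, and 8 were lower at an unadjusted p under 0.05. HLA-DPA1, an alpha chain of the family, had a change of -1.88 ± 0.67 that did not pass (adjusted p = 0.171). Markers of plasmacytoid dendritic cells moved with these groups: 3 of 7 fell (5 adjusted over the list alone), with a median of -0.86 (list adjusted p = 1.01e-06, and adjusted p = 0.0387 with an estimated correlation). LILRA4, a receptor of those cells, fell by 1.14 ± 0.15, and TLR7, an endosomal receptor outside that list, fell by 3.02 ± 0.27. Proliferation genes were high on both sides, with a mean of 9.04 ± 0.04 (SD, n = 3) in ITTP and 8.89 ± 0.37 (SD, n = 2) in DP cells. By limma 0 of 36 cell cycle genes passed, 1 higher and 1 lower at an unadjusted p under 0.05.

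In all, 548 of 13282 genes changed between ITTP and DP cells, 310 upward and 238 downward, 307 of them at least 2-fold (limma, adjusted p under 0.05), and 11 of 30 gene lists passed. The count was 327 without ITTP replicate 2 and 212 without DP replicate 1, where the lone DP sample was assumed to vary like the other groups. The changes of TOX2, PRKCA, JCHAIN, IGLL1 and TLR7 are lower bounds, since the dimmer mean lay below the filter level.

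The step from DP to SP4 cells asked what accompanies commitment to the CD4 lineage. The recombination machinery and the cortical program were switched to low levels: RAG1 (206591_at) fell from 10.42 ± 0.14 (SD, n = 2) to 5.07 ± 0.11 (SD, n = 3), at least 40.6-fold (adjusted p = 5.99e-08), and RAG2, its partner, fell by 3.36 ± 0.20. CD8A fell by 4.24 ± 0.25, CD1E, a lipid-antigen presenting molecule, 24.3-fold, and DNTT, which adds nucleotides at receptor gene junctions, fell by 4.93 ± 0.86. The DNTT change was -3.46 without DP replicate 1 and -6.40 without DP replicate 2. In the other direction, the orphan receptor GPR171 (207651_at) rose at least 34.3-fold, from 5.76 ± 0.15 (SD, n = 2) to 10.85 ± 0.37 (SD, n = 3), the membrane adaptor ANK3 at least 23.5-fold and GIMAP4 at least 17.1-fold.

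All 16 tested cortical thymocyte and V(D)J recombination genes fell, over all genes and adjusted over the list alone, with a median log2 change of -3.67 (list adjusted p = 1.66e-103, and adjusted p = 0.00281 with an estimated correlation). Proliferation genes fell with them. Of 36 cell cycle genes 23 fell (32 adjusted over the list alone), with a median of -1.46 (list adjusted p = 1.99e-21, and adjusted p = 0.172 with an estimated correlation). The spindle checkpoint kinase TTK fell by 2.54 ± 0.23, BUB1B, of the same checkpoint, fell by 2.79 ± 0.41 and the mitotic kinase AURKB fell by 1.45 ± 0.18. The mean of this list stood apart in SP4 replicate 3, at 8.25 against 6.75 and 6.80 in the other SP4 samples.

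Genes of naive T cell egress and homing rose in SP4 cells, 6 of 12 over all genes (7 rose and 1 fell adjusted over the list alone, list adjusted p = 9.92e-16, and adjusted p = 0.00603 with an estimated correlation). FOXO1, a transcription factor of T cell quiescence, rose 11.9-fold, CCR7, a lymph node homing receptor, at least 8.82-fold, KLF2 4.83-fold and the egress receptor S1PR1 3.85-fold. Of 7 GIMAP genes 6 rose, over all genes and adjusted over the list alone, with a median of 2.62 (list adjusted p = 2.53e-21, and adjusted p = 0.0161 with an estimated correlation). Genes of positive selection and receptor response rose again, 6 of 12 (9 adjusted over the list alone), with CD27, a costimulatory receptor, at 1.84 ± 0.21 and EGR3 at 2.14 ± 0.32 (list adjusted p = 1.2e-06, and adjusted p = 0.0307 with an estimated correlation). Receptor complex genes went both ways, with 6 of 21 up and 3 down (7 and 3 adjusted over the list alone), and their list did not pass.

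MHC class I, interferon-stimulated and cytokine receptor genes rose at the same step. Of 13 MHC class I and antigen processing genes 5 rose (9 adjusted over the list alone), HLA-B 10.2-fold, HLA-C 6.19-fold and NLRC5, the transactivator of class I genes, 9.24-fold (list adjusted p = 6e-16, and adjusted p = 0.0161 with an estimated correlation). Of 27 interferon-stimulated genes 16 rose (19 adjusted over the list alone), IFI44L by 3.90 ± 0.49, GBP2 by 2.80 ± 0.31 and RSAD2 by 2.06 ± 0.16 (list adjusted p = 1.66e-15, and adjusted p = 0.0161 with an estimated correlation). Of 17 cytokine receptor genes 8 rose (9 rose and 1 fell adjusted over the list alone), including IL6ST, the shared chain gp130, by 2.96 ± 0.20 and IL2RB by 2.15 ± 0.22 (list adjusted p = 8.18e-13, and adjusted p = 0.0122 with an estimated correlation). The ribosomal protein list passed upward with 2 of 58 genes up and 1 down, the same numbers as adjusted over the list alone (list adjusted p = 0.0186, and adjusted p = 0.673 with an estimated correlation). That call ended without DP replicate 1 (adjusted p = 0.504), SP4 replicate 2 (0.0716) or SP4 replicate 3 (0.0897), within a range of 2.56e-05 to 0.504 over its alternatives.

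Between DP and SP4 cells 1159 genes changed, 565 up and 594 down, 662 of them at least 2-fold, and 9 of 30 lists passed, of which 7 also passed with an estimated correlation. The gene count was 709 without DP replicate 1, 666 without DP replicate 2, where the lone DP sample was assumed to vary like the other groups, and 764 without SP4 replicate 2. The balance was 478 up and 712 down on the values as deposited and 538 and 657 with a 75th percentile shift, and it turned without SP4 replicate 1, to 438 and 429. The changes of RAG1, RAG2, DNTT, GPR171, ANK3, GIMAP4, TTK, AURKB, CCR7, GBP2 and RSAD2 are lower bounds.

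**Figure D3:**
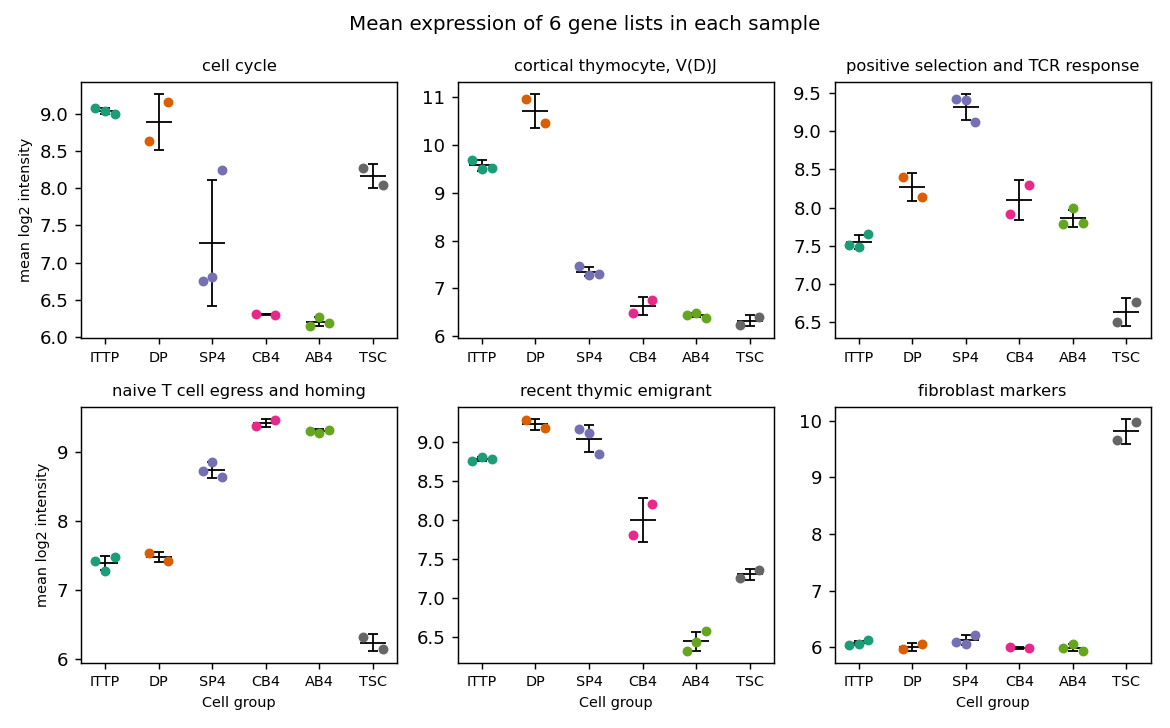
Points give the mean log2 intensity (y axis) of the tested genes of 6 gene lists in each sample, grouped by cell type (x axis), and the bars show the group mean and SD. The cell cycle mean is 8.25 in SP4 replicate 3 and 6.75 and 6.80 in the other SP4 samples, and the fibroblast marker mean is 9.81 in stromal cells.

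The comparison of CB4 with SP4 cells set naive CD4+ T cells in cord blood against the most mature CD4+ thymocytes. The groups differ in tissue of origin as well as in stage, so tissue and stage cannot be told apart here. Among receptor response genes, EGR1 (201694_s_at) fell from 10.04 ± 0.29 (SD, n = 3) to 5.93 ± 0.04 (SD, n = 2), 17.3-fold (adjusted p = 9.56e-07), and EGR3 at least 9.32-fold. EGR1 also stood at 9.20 and 9.04 in the stromal samples, so a high level is not particular to T cells. TOX2 (228737_at) fell at least 26.7-fold, from 9.70 ± 0.44 (SD, n = 3) to 4.97 ± 0.04 (SD, n = 2), and CCR9, a receptor for a thymic chemokine, 17.3-fold. The prostaglandin receptor PTGER2 rose at least 13.9-fold, the cytotoxic granule protease GZMA 13.6-fold, from 6.36 ± 1.05 (SD, n = 3) to 10.13 ± 0.62 (SD, n = 2), and the nucleoside enzyme UPP1 12.4-fold (203234_at, adjusted p = 8.8e-07). The log2 change of GZMA, 3.77 ± 0.50, was 4.37 without SP4 replicate 3. None of the 15 lists that passed here did so with an estimated correlation, so each list result below carries that p as well.

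Several programs seen in thymocytes were lower in cord blood, among them genes of positive selection and interferon response, which had risen from DP to SP4 cells. Of 12 positive selection and receptor response genes 5 fell and 1 rose (8 and 1 adjusted over the list alone), with NR4A3, a nuclear receptor, at -1.40 ± 0.17 and the selection-related factor TOX at -1.64 ± 0.21 (list adjusted p = 6.52e-11, and adjusted p = 0.106 with an estimated correlation). Of 16 cortical genes 5 fell (6 adjusted over the list alone), CD1E at -1.83 ± 0.18 and CD8A at -1.44 ± 0.25 (list adjusted p = 2.77e-05, and adjusted p = 0.216 with an estimated correlation). Of 8 recent thymic emigrant genes 4 fell (5 fell and 1 rose adjusted over the list alone), NREP at -1.82 ± 0.16, with a list median of -0.81 (list adjusted p = 3.49e-06, and adjusted p = 0.106 with an estimated correlation). Of 27 interferon-stimulated genes 7 fell and 1 rose (7 and 2 adjusted over the list alone), RSAD2 at -1.48 ± 0.16 and IFIT1 at -1.52 ± 0.23 (list adjusted p = 0.00776, and adjusted p = 0.368 with an estimated correlation). Of 21 receptor complex genes 4 fell and 1 rose, the same numbers as adjusted over the list alone, among them the adaptor LAT at -0.97 ± 0.16 (list adjusted p = 0.021, and adjusted p = 0.368 with an estimated correlation). That list's call ended without CB4 replicate 1 (adjusted p = 0.056, within 0.00407 to 0.056 over its alternatives). Of 36 cell cycle genes 10 fell (13 adjusted over the list alone, list adjusted p = 7.55e-06, and adjusted p = 0.506 with an estimated correlation), with a median of -0.71 that became -0.21 without SP4 replicate 3, the sample with the highest cell cycle level of its group.

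Homing genes and the GIMAP family rose further. Of 12 egress and homing genes 4 rose (7 rose and 1 fell adjusted over the list alone), KLF2 4.03-fold, CCR7 3.99-fold and the complement regulator CD55 2.61-fold (list adjusted p = 1.27e-04, and adjusted p = 0.106 with an estimated correlation). Of 7 GIMAP genes 4 rose, over all genes and adjusted over the list alone, with a median of 1.22 (list adjusted p = 2.6e-05, and adjusted p = 0.126 with an estimated correlation). Of 26 memory and effector genes 3 rose, 5 adjusted over the list alone (list adjusted p = 0.021, and adjusted p = 0.561 with an estimated correlation), GZMA among them. That call ended without SP4 replicate 1 (adjusted p = 0.0596, within 0.00433 to 0.0596 over its alternatives). Ribosomal protein genes went up in 9 of 58 cases and down in 1 (11 and 4 adjusted over the list alone, list adjusted p = 0.0177, and adjusted p = 0.561 with an estimated correlation). The ribosomal call ended without SP4 replicate 1 (adjusted p = 0.076) and without CB4 replicate 2 (0.0524), within 1.69e-04 to 0.076 over its alternatives. Oxidative phosphorylation genes went up in 8 of 66 cases and down in 4 (11 and 4 adjusted over the list alone, list adjusted p = 0.0299, and adjusted p = 0.726 with an estimated correlation). Their call ended without SP4 replicate 1 (adjusted p = 0.204), without CB4 replicate 1 (0.755), after a shift to a common 75th percentile (0.135) and on the values as deposited (0.127), within 3.6e-04 to 0.755.

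MHC class II genes and markers of some other blood cells rose at the same time. Of 10 MHC class II genes 8 rose, over all genes and adjusted over the list alone, with a median of 1.29 (list adjusted p = 2.42e-05, and adjusted p = 0.126 with an estimated correlation). HLA-DPA1 rose by 2.88 ± 0.67 (3.47 without CB4 replicate 1), a call that ended without CB4 replicate 2 (change 2.30, adjusted p = 0.113, within 0.00399 to 0.113 over its alternatives). Without that sample the list kept its call (median 1.16, adjusted p = 0.00606), with 1 of 10 genes up. Plasmacytoid dendritic cell markers rose in 5 of 7 cases, 6 adjusted over the list alone (list adjusted p = 6.14e-05, and adjusted p = 0.112 with an estimated correlation). TCF4, a transcription factor of those cells, rose by 1.97 ± 0.30. A further list of 18 plasmacytoid genes, described with the additional observations, gave no call here (list test p = 0.393, and p = 0.461 with an estimated correlation). Of its genes 0 rose and 0 fell. JCHAIN and TLR7, which were high in ITTP cells (7.51 and 7.76), averaged 4.63 and 4.8 in CB4 cells, below the filter level. IRF8 and LILRA4 went the other way, at 8.69 and 6.7 in CB4 against 6.82 and 6.17 in SP4 cells. The rise of the marker list is therefore not shown to come from plasmacytoid cells. Whether genes shared with B cells carried it was not tested. B cell markers rose in 3 of 10 cases, 4 adjusted over the list alone (list adjusted p = 0.00984, and adjusted p = 0.362 with an estimated correlation), and without CB4 replicate 2 the call ended (adjusted p = 0.162, within 4.24e-13 to 0.162). Erythroid markers rose in 3 of 6 cases, 4 adjusted over the list alone (list adjusted p = 0.00778, and adjusted p = 0.362 with an estimated correlation), and again the call ended without CB4 replicate 2 (adjusted p = 0.408, within 2.8e-19 to 0.408). The monocyte, macrophage and dendritic cell (list adjusted p = 0.0602, 1 of 8 up), NK cell (0.842, 0 of 4) and platelet (0.726, 0 of 5) lists did not pass. Of those 8 monocyte, macrophage and dendritic cell genes 4 were higher and 0 lower at an unadjusted p under 0.05. S100A8, on that list, rose by 3.79, and by 2.13 without CB4 replicate 2. It ranged from 6.90 to 10.23 in CB4 and from 4.52 to 5.03 in SP4 samples. The erythroid gene HBB rose by 3.17, and by 1.39 without CB4 replicate 2, and ranged from 9.27 to 12.82 in CB4 samples. The 3' minus 5' difference of the GAPDH control probe sets, a sign of RNA integrity, averaged 2.36 on A arrays of CB4 samples and 1.70 on those of SP4 samples, while that of ACTB went the other way, 4.61 against 5.54.

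Between SP4 and CB4 cells 1625 genes changed, 771 up and 854 down, 625 of them at least 2-fold, and 15 of 30 lists passed. The gene count was 1030 without SP4 replicate 2 and 517 without CB4 replicate 1, where the lone CB4 sample was assumed to vary like the other groups. The balance turned without CB4 replicate 2 (761 up and 653 down), with a 75th percentile shift (759 and 739) and with each probe set as its own feature (1605 and 1474). The changes of EGR3, TOX2, PTGER2, CD1E and S100A8 are lower bounds.

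The comparison of AB4 with CB4 cells set naive CD4+ T cells of adult blood against those of cord blood, a contrast in which the labels name recent thymic emigrants as a subject. SOX4 (201416_at), a transcription factor of immature lymphocytes, was at least 34.3-fold lower in adult cells: it stood at 10.87 ± 0.07 (SD, n = 2) in cord blood and at 5.76 ± 0.42 (SD, n = 3) in adult blood (adjusted p = 6.99e-07). RGS1, a regulator of G protein signalling, fell at least 22.2-fold, AUTS2 20.3-fold, TCF4 at least 11.9-fold and IGF2BP3, an RNA-binding protein of fetal cells, at least 9.64-fold. The log2 change of IGF2BP3, -3.27 ± 0.42, was -4.04 without CB4 replicate 1 and -2.49 without CB4 replicate 2. GZMA, which had risen from SP4 to CB4 cells, fell by 3.10 ± 0.50. Adult cells had more GBP5 (229625_at), an interferon-inducible GTPase, which rose at least 10.1-fold from 4.95 ± 0.03 (SD, n = 2) to 8.30 ± 0.09 (SD, n = 3), more of the mineralocorticoid receptor NR3C2, at least 8.40-fold, and more of the TGF-beta coreceptor TGFBR3, at least 4.71-fold.

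The recent thymic emigrant list had the lowest adjusted p of the lists in this contrast. Of its 8 tested genes 3 fell, over all genes and adjusted over the list alone: SOX4, NREP at -3.09 ± 0.16 and TOX at -2.21 ± 0.21 (list adjusted p = 7.6e-26, and adjusted p = 0.0183 with an estimated correlation). CCR9 and CD38, on the same list, changed by -0.62 ± 0.34 (adjusted p = 0.366) and -0.41 ± 0.17 (adjusted p = 0.222). The remaining genes, PTK7, PECAM1 and CR2, did not pass either. The mean level of the list was 7.8 and 8.2 in the CB4 samples. It ran from 8.76 to 8.81 in ITTP and from 8.85 to 9.17 in SP4 samples, so a high level is not particular to emigrants. Cord and adult blood also differ in donor age, so age and emigrant content cannot be told apart here. The list's median was -0.58, and it was -0.92 without CB4 replicate 1 and -0.32 without CB4 replicate 2. Among genes of other lists, BCL2A1, a survival factor of the BCL2 family, rose by 1.72 ± 0.13, and TNFAIP3 fell by 1.37 ± 0.13. Neither of their lists passed. Cell cycle genes were low in both blood groups, with mean levels of 6.30 ± 0.01 (SD, n = 2) in CB4 and 6.20 ± 0.06 (SD, n = 3) in AB4 cells.

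Lists for MHC class II genes and for some other blood cells were lower in adult than in cord blood. The NK cell (list adjusted p = 0.712) and platelet (0.816) lists did not pass. Of 7 plasmacytoid dendritic cell markers 3 fell, 5 adjusted over the list alone (list adjusted p = 5.27e-08, and adjusted p = 0.098 with an estimated correlation). Among them were TCF4 and the adaptor BLNK, at -1.06 ± 0.17. JCHAIN and TLR7 lay below the filter level in cord and in adult blood, so the fall is not shown to come from plasmacytoid cells. The further list of 18 plasmacytoid genes also tested lower, with 0 genes called (list test p = 0.00553, and p = 0.0576 with an estimated correlation, median -0.21). Of 10 MHC class II genes 1 fell, also adjusted over the list alone (list adjusted p = 0.00334, and adjusted p = 0.548 with an estimated correlation). Of 10 B cell markers 2 fell, 3 adjusted over the list alone (list adjusted p = 0.0242, and adjusted p = 0.669 with an estimated correlation). Of 6 erythroid markers 1 fell, 2 adjusted over the list alone (list adjusted p = 0.016, and adjusted p = 0.669 with an estimated correlation). Of 8 monocyte and dendritic cell markers limma called 0 over all genes, with 2 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (list adjusted p = 0.0351, and adjusted p = 0.669 with an estimated correlation). Without CB4 replicate 2 the last 4 calls ended, with adjusted p = 0.323 for MHC class II (3.9e-08 to 0.323 over its alternatives), 0.636 for B cells (7.94e-15 to 0.636), 0.928 for erythroid cells (1.79e-22 to 0.928) and 0.543 for monocytes (8.16e-04 to 0.543). With the stricter filter the B cell (adjusted p = 0.122) and erythroid (0.111) calls also ended, and so did the monocyte call with no filter (0.19), with a 75th percentile shift (0.0603) and on the values as deposited (0.0571). Of 66 oxidative phosphorylation genes 3 fell, and adjusted over the list alone 5 fell and 1 rose (list adjusted p = 0.0172, and adjusted p = 0.817 with an estimated correlation). Their call ended without CB4 replicate 1 (adjusted p = 0.759, within 3.81e-05 to 0.759), with the 75th percentile shift (0.0656) and on the values as deposited (0.0571). The GAPDH 3' minus 5' difference averaged 1.61 on A arrays of AB4 samples and 2.36 on those of CB4 samples, while that of ACTB averaged 4.93 and 4.61.

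Between CB4 and AB4 cells 597 genes changed, 339 up and 258 down, 259 of them at least 2-fold, and 7 of 30 lists passed, of which 1 also passed with an estimated correlation. The gene count was 160 without CB4 replicate 1, where the lone CB4 sample was assumed to vary like the other groups, and 316, 301 and 264 without AB4 replicates 1, 2 and 3, and the list count was 3 without CB4 replicate 2. The balance turned without CB4 replicate 1 (65 up and 95 down), without CB4 replicate 2 (304 and 350) and in the test against a fold change of 1.2 (71 and 80). The changes of SOX4, RGS1, TCF4, IGF2BP3, GBP5, NR3C2, TGFBR3, TOX, BCL2A1 and BLNK are lower bounds.

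Thymic stromal cells were compared with the mean of the thymocyte groups (ITTP, DP and SP4). ACTA2 (200974_at), smooth muscle actin, was at least 207-fold higher in stromal cells, with a log2 change of 7.70 ± 0.15 (adjusted p = 8.52e-13). The gap junction gene GJA1 was at least 145-fold and the matrix gene POSTN at least 133-fold higher. INHBA, a subunit of activin, was at least 116-fold higher. FN1, fibronectin, was 84.5-fold and COL3A1, a fibrillar collagen, at least 51.5-fold higher. CD3D fell by 7.37 ± 0.14 from thymocytes to stromal cells, TRBC1 83.0-fold, PTPRC at least 43.7-fold, and the T cell kinase LCK fell by 5.37 ± 0.22.

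Of 18 fibroblast and mesenchyme markers 16 rose and 1 fell, the same numbers as adjusted over the list alone, with a median of 3.82 (list adjusted p = 4.09e-47, and adjusted p = 0.014 with an estimated correlation). Of 7 thymic epithelial markers 1 rose, also adjusted over the list alone: KRT18, a keratin of simple epithelia that other cells also make, by 4.92 ± 0.17. Its list did not pass (adjusted p = 0.213). By limma 0 of 6 endothelial markers passed, and 0 did at an unadjusted p under 0.05. In stromal cells the fibroblast list averaged 9.81, the endothelial list 6.03 and the monocyte, macrophage and dendritic cell list 6.07. The stromal profile is thus not shown to cover endothelial or myeloid cells of the thymus. Of 19 glycolysis genes 10 rose, over all genes and adjusted over the list alone, among them the glucose transporter SLC2A1 by 1.27 ± 0.13, without a call for the list (adjusted p = 0.567). The memory and effector list, which holds several genes that fibroblasts also make, went both ways, with 10 of 26 up and 4 down, among the former LGALS1 at 6.61 ± 0.35 and ANXA2 at 5.52 ± 0.35. Its median was -0.07 and its mean 0.99, and the list did not pass.

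T cell lists were lower in stromal cells. Of 21 receptor complex genes 19 were lower, over all genes and adjusted over the list alone (list adjusted p = 1.08e-40, and adjusted p = 0.014 with an estimated correlation), and of 16 cortical genes 15 fell, 16 adjusted over the list alone (list adjusted p = 2.88e-14, and adjusted p = 0.0442 with an estimated correlation). Of 12 egress genes 7 fell and 2 rose, the same adjusted over the list alone, with LEF1 at -4.70 ± 0.16 and IL7R at -4.64 ± 0.27 (list adjusted p = 1.58e-04, and adjusted p = 0.0759 with an estimated correlation). Of 12 positive selection genes 9 fell, also adjusted over the list alone (list adjusted p = 0.00134, and adjusted p = 0.172 with an estimated correlation), and of 7 GIMAP genes 6 fell, also adjusted over the list alone (list adjusted p = 0.00117, and adjusted p = 0.172 with an estimated correlation). Of 8 recent thymic emigrant genes 7 fell and 1 rose, the same adjusted over the list alone, with CCR9 at -3.80 ± 0.29 and PTK7, a receptor-like gene of many tissues, at 0.82 ± 0.12 (list adjusted p = 0.00343, and adjusted p = 0.0956 with an estimated correlation). Of 11 NF-kB pathway genes 6 fell, also adjusted over the list alone, LTB at -5.26 ± 0.14 (list adjusted p = 0.0226, and adjusted p = 0.172 with an estimated correlation).

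In all, 6373 of 13761 genes differed between stromal cells and thymocytes, 2911 higher and 3462 lower, 2671 of them at least 2-fold, and 8 of 30 lists passed, of which 3 also passed with an estimated correlation. The median change of all genes was -0.08, and -0.11 on the values as deposited. The GAPDH 3' minus 5' difference averaged 2.21 on A arrays of stromal samples, against 1.51, 1.48 and 1.70 in ITTP, DP and SP4 samples, while that of ACTB averaged 4.86 against 5.83, 5.12 and 5.54. The balance turned without TSC replicate 1 (2257 higher and 2239 lower), where the lone stromal sample was assumed to vary like the other groups, and in the test against a fold change of 1.2 (2062 and 1954). The changes of ACTA2, GJA1, POSTN, INHBA, COL3A1, CD3D, PTPRC, LCK, KRT18, LGALS1 and LTB are lower bounds.

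Over the 5 comparisons 50 of 150 list results passed, 16 of them also with an estimated correlation and 40 by fry, which asks whether a list's genes move one way without comparing them with other genes. The lists that passed in no comparison were regulatory T cell (lowest adjusted p = 0.79), fetal-type regulators (0.283), glycolysis (0.258), BCL2 family (0.802), and the markers of thymic epithelium (0.213), endothelium (0.244), NK cells (0.712) and platelets (0.531). The median, mean and test of a list differed in sign in 20 of the 150 results, with no passing list among them.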

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

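Named genes and lists were followed under the alternatives of array scale, filter, arrays in the fit and title number, and without each sample. Under the other alternatives only the numbers of genes were taken. No named gene or list that passed changed direction where it was followed. The balance of genes up and down turned in all comparisons except DP minus ITTP, in the settings given in the report. Of the genes named and past the threshold, 30 of 56 between ITTP and DP kept their call in every alternative followed. Between DP and SP4 55 of 76 did, and between SP4 and CB4 42 of 93. The numbers were 17 of 37 between CB4 and AB4 and 103 of 122 for stromal cells that kept their call. Of the lists that passed, 11 of 11, 8 of 9, 9 of 15, 2 of 7 and 8 of 8 did. Leaving out each sample in turn, which leaves a lone sample in DP, CB4 or TSC that is assumed to vary like the other groups, gave 212 to 670 genes for DP minus ITTP, 666 to 1271 for SP4 minus DP, 517 to 1786 for CB4 minus SP4, 160 to 681 for AB4 minus CB4, 4496 to 6474 for stromal cells and 3631 to 4503 across the T lineage groups, and 11 to 15, 8 to 9, 12 to 16, 3 to 9 and 8 to 9 lists in the order of the comparisons. The lowest counts came without DP replicate 1, DP replicate 2, CB4 replicate 1 (CB4 minus SP4 and AB4 minus CB4), TSC replicate 1 and AB4 replicate 2. With each probe set as its own feature, which tests more features, the counts were 914, 2123, 3079, 1188 and 13789, and 8784 across the T lineage groups. Array quality weights gave 1160 genes for DP minus ITTP, 1875 for SP4 minus DP and 6851 across groups, and the cause was not tested. A test against a fold change of 1.2, a stricter question by construction, gave 230, 627, 555, 151 and 4016, and it has no count across groups. The stricter filter left 4 lists for AB4 minus CB4, and the cause was not tested. With values as deposited, chosen after seeing the data, the counts were 570, 1190, 1459, 494 and 6578, and 4338 across groups. The title number as a replicate block gave 395, 1071, 1214, 409 and 6104, and 3953 across groups. ITTP and SP4 samples of the same number correlated best with each other in 3 of 3 cases (r across genes from 0.0811 to 0.243), but the labels do not say that numbers share a donor, so numbers were not used to pair samples. Without SP4 replicate 3 the counts were 1239 for SP4 minus DP and 1429 for CB4 minus SP4, and without CB4 replicate 2 they were 1414 for CB4 minus SP4 and 654 for AB4 minus CB4. Alternatives for a floor on low values did not apply, since the values have none, and quantile normalization, planned as an alternative, was already in use. In simulated data from 23.9% to 52.2% of genes changed 1.5-fold were recovered, so changes of that size were often missed there with this number of arrays. These shares need not hold for the real data, where more genes were called and genes are not independent.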

Other observations

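Some tests were chosen only after the result was seen. They concern other cell types' markers in ITTP, CB4 replicate 2 alone, DP cells in SP4 replicate 3 and array scale. The tests of the new plasmacytoid list from ITTP to DP and of the new B cell list from SP4 to CB4 were set before. Results of these lists in other comparisons carried no prediction. The genes of the next paragraph were chosen by no fixed rule, after their values were seen, from the 10 of each group with the largest gap to all other samples, and those of the paragraph after it were chosen after their values were seen.

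Each T lineage group had genes that were highest in all of its samples. Among the 4408 genes that differed across the groups, 417 were higher in every ITTP sample than in every other T lineage sample (9.46%, where chance gives 0.35%), 302 in DP (6.85%, chance 1.28%), 201 in SP4 (4.56%, chance 0.35%), 466 in CB4 (10.6%, chance 1.28%) and 391 in AB4 (8.87%, chance 0.35%). The chance shares hold for random orders of unselected genes, and these genes were selected for differing between the groups, so shares above chance follow in part from that selection. ITTP cells held FXYD2, a regulator of the sodium pump, at 8.80 ± 0.52 (SD, n = 3) against 6.19 in the next group, and TNFSF4, the ligand OX40L, at 8.59 ± 0.21 against 6.81. DP cells held CPLX1, a gene of vesicle release, at 7.69 ± 0.03 (SD, n = 2) against 5.20. SP4 cells held the serotonin receptor HTR2B at 8.20 ± 0.38 (SD, n = 3) against 5.34, the phosphodiesterase PDE4D at 10.34 ± 0.08 against 8.42, and SPRY2, a feedback inhibitor of receptor signalling, at 7.46 ± 0.38 against 5.50. CB4 cells held ANKRD55 at 10.19 ± 0.42 (SD, n = 2) against 8.50 and the NF-kB modulator NFKBIZ at 9.64 ± 0.04 against 8.19. AB4 cells held STAT4, which carries interleukin-12 signals, at 9.55 ± 0.03 (SD, n = 3) against 7.59 in cord blood.

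Some genes varied widely within the thymic groups. LIN28B, an RNA-binding protein of fetal cells, ranged from 4.31 to 9.43 in ITTP, 4.55 to 8.17 in DP and 4.44 to 5.94 in SP4 samples, and from 4.34 to 4.59 in the blood groups. In each thymic group the sample highest in LIN28B was also the highest in HMGA2, a chromatin protein of fetal cells that ranged from 5.80 to 8.70 in ITTP, and the lowest in DNTT, which ranged from 8.95 to 11.70 in ITTP and from 9.05 to 11.99 in DP. No correlation is given, since the samples fall into clusters by group.

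Plasmacytoid dendritic cell markers were higher in ITTP than in DP samples, with a median change of -0.86. Plasmacytoid cells inside the ITTP gate are a candidate explanation, since a new list of their genes was also lower in DP (p = 0.00558 and p = 0.0519 with an estimated correlation, 3 of 18 genes down and 1 up), and the gate takes CD4+ cells without CD3 or CD8, although it also asks for low CD34, whose effect on such cells was not tested. Against a clean reading, 17 of the 18 genes were at or above the filter level in DP cells, and the new list also tested lower in SP4 than in DP (p = 3.17e-05 and p = 0.104 with an estimated correlation, 5 of 18 down, although the median was 0.04). A lower share of T lineage cells in ITTP stays open: 33 markers of B, NK, erythroid, platelet and monocyte, macrophage and dendritic cells had a median change of 0.035 (quartiles -0.15 and 0.11), but only 9 of them reached the stricter filter level in either group, and the 8 monocyte, macrophage and dendritic cell markers had a median of -0.59. JCHAIN, TLR7 and IRF8, abundant in plasmacytoid cells, averaged 7.51, 7.76 and 9.03 in ITTP, and expression by the progenitors themselves stays open as untested.

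MHC class II genes and B cell markers were higher in CB4 than in SP4 samples. CB4 replicate 2 alone is argued against as the whole source of the class II change, since the median without it was 1.16, against 1.29 with it. This does not extend to the B cell markers, whose median was 0.31 with that sample and 0.20 without it. Whether B cells in the CB4 samples contributed cannot be told apart from expression by the T cells: a new list of 15 B cell genes gave p = 0.15 (p = 0.3 with an estimated correlation, 3 up and 1 down, median 0.22), and the bound set beforehand, that a p of 0.05 or more counts against B cells, was wrong, because a p that misses the threshold excludes nothing. The same list tested lower in AB4 than in CB4 samples (list test p = 0.00493, and p = 0.116 with an estimated correlation, 1 of 15 down, median -0.14). Of those 15 genes 12 were at or above the filter level in SP4 cells. The gate asked for CD3 and CD4, and how far it removed B cells was not tested. The B cell genes PAX5 and MS4A1 ranged from 6.79 to 9.31 and from 6.62 to 8.06 between the CB4 samples. They reached at most 6.36 and 6.68 in SP4 and 6.64 and 6.82 in AB4 samples. The PAX5 change from SP4 to CB4 was 1.89, and 0.63 without CB4 replicate 2. The difference between thymus and blood stays open as untested.

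Cell cycle genes were high in SP4 replicate 3. DP cells inside that sample are argued against: the cell cycle genes would need a median DP share of 46% (quartiles 35.7 and 64.1, 33 genes), where 15 cortical thymocyte genes gave a median of -0.182% (quartiles -1.23 and 1.29). The scale of its arrays is argued against as well, since 4665 genes of like brightness differed from the other SP4 samples by a median of 0.045 (quartiles -0.10 and 0.19) on the values as deposited, where the cell cycle genes differed by 1.35 (quartiles 0.88 and 2.07). A larger share of dividing SP4 cells in that sample may account for the pattern, a hypothesis for which no test was run.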
